A study of Mus musculus with 6 samples.

How the data were processed

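Polyadenylated RNA of sorted cardiomyocytes was measured in 6 libraries, 2 each from mice given AAV-GFP, AAV-XBP1S or AAV-ATF6N at postnatal day 1 and analysed at 4 weeks, per the labels. The labels name a PureLink micro-scale RNA kit, the SMART-Seq v4 kit for cDNA, while a description names SMART-Seq2, and Nextera XT for library construction. These kits amplify full-length cDNA and do not mark strand, so reads of overlapping or antisense genes cannot be told apart. Reads carried no molecular identifiers that a source used here names, and intervals and floors given in the text cover counting error only.

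The table of counts deposited by the authors holds whole-number read counts per gene for 23337 genes and 6 libraries, made with STAR and featureCounts on mm10, per the submitters' processing notes and the file header. Versions, the annotation release and the strand setting are not given in the sources used here. The authors also deposited a table for each comparison against AAV-GFP. Per the file headers, it gives the mean normalized signal per gene, that is the mean of counts divided by size factors over 4 libraries, a log2 fold change, its standard error and a Wald statistic as scores, and p-values with Benjamini-Hochberg adjustment. The submitters' processing notes name DESeq2 and DESeq. These tables were used for the numbers of genes past an adjusted p of 0.05, for the values of Xbp1 and Atf6 and for a comparison of their log2 fold changes with those computed here. All 6 columns of counts were used, and 0 columns of per-sample values were left out.

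Groups were taken from the labels' treatment. The total counts ran from 67702482 to 112049342 per library, and 3 counts came to 0.0305 to 0.0459 CPM. Genes were kept by edgeR's filterByExpr with the group and a count minimum of 10, which left 14587. With TMM normalization, edgeR's quasi-likelihood test (glmQLFit without robust estimation, edgeR 4.0.16, R 4.3.3) was fitted to all 6 libraries with the group as the only term, which left 3 residual degrees of freedom. The prior degrees of freedom were 3.73 and the common dispersion 0.0921. The comparisons were AAV-XBP1S against AAV-GFP, AAV-ATF6N against AAV-GFP and AAV-ATF6N against AAV-XBP1S, each two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the test's F. An exact permutation test of 2 against 2 libraries cannot go below 33.3% two-sided, so none was used. CPM are counts scaled to the TMM-adjusted library size. Where a group had no count, the fold was computed against a floor of 3 counts over the group.

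The following were fixed before the data were examined: 33 gene lists, the tests, the rule for named genes and most alternatives. The lists were targets preferred by XBP1s, targets preferred by ATF6, the PERK, ATF4 and CHOP stress response, ER chaperones and oxidoreductases, ER-associated degradation, ER translocation with signal peptidase and N-glycosylation, ER to Golgi transport, hexosamine biosynthesis, the sarcomere, calcium handling with T-tubule and ion channels, the fetal and hypertrophic stress program, oxidative phosphorylation, fatty acid uptake and oxidation, glycolysis, the tricarboxylic acid cycle, sterol and fatty acid synthesis, phospholipid synthesis, cytosolic heat shock, NRF2 and antioxidant genes, lysosome and autophagy, p53 and apoptosis, the cell cycle, the interferon response, immediate early and dissociation genes, the proteasome, extracellular matrix, and markers of endothelium, fibroblasts, macrophages and leukocytes, smooth muscle and pericytes, erythroid cells, epicardium and Schwann cells, and atrial cardiomyocytes. Symbols missing from the table were matched through RefSeq synonyms, and Hbb-bt stayed unmatched. Lists were tested with limma camera (3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 33 lists of a comparison. With the correlation estimated per list none of the calls held, and that adjusted p stands beside each called list. In that form camera takes its degrees of freedom from the libraries, 3 here. With the preset correlation it takes them from the number of genes. The estimated correlation was below the preset 0.01 for targets preferred by ATF6 (-0.0512) and the cell cycle (-0.0189). A higher correlation is therefore not what removed those calls. Lists overlap: targets preferred by XBP1s share 14 members with ER translocation, 6 with ER to Golgi transport and 5 with the chaperones, and targets preferred by ATF6 share 11 with the chaperones.

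The named genes were Xbp1 and Atf6; the 12 higher and 10 lower genes of smallest p per comparison (8 and 8 in the direct one) among those past the threshold with an absolute log2 fold change of at least 1, a mean of at least 5 CPM in the higher group and groups that did not overlap, leaving out predicted, pseudogene and mitochondrial symbols; up to 4 members of smallest p per list; 24 fixed ER stress and cardiac genes; and up to 6 genes per direction called in both comparisons against AAV-GFP, with any called in opposite directions. Some genes that the rule names are not reported here. For chance values of the correlation and covariance of fold changes, 20 data sets of unchanged groups were simulated with the fitted dispersions, and correlations were computed over genes with at least 10 counts in every library. The plan had been to keep the measured control libraries in these simulations; the control libraries were simulated instead.

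The test was checked on simulated data over 14587 genes with 100 genes changed 4-fold and 100 changed 16-fold. In the simulated AAV-XBP1S comparison it recovered 70% and 90%, with 6 false among 166 calls, and in the simulated AAV-ATF6N comparison 74% and 95%, with 10 false among 179 calls. A gene-length trend planted in 1 library left a correlation of fold change with length of 0.441, and 0.00335 after the offset described below. A planted list ranked 1, and 5 of 200 random lists had p below 0.05. The simulated genes were independent, with the same dispersion in all groups. In the measured data the chi-square per gene between replicates was 749, 282 and 11.8 in AAV-GFP, AAV-XBP1S and AAV-ATF6N. The estimated correlation reached 0.794 in the oxidative phosphorylation list. These checks therefore do not give the error rates of the measured comparisons. Alternatives fixed beforehand were DESeq2 size factors, no filter, a filter of 50 counts in 2 libraries, DESeq2 1.42.0, a fit of the groups compared alone, the replicate number as a block, robust spread, each library left out in turn, and for lists an estimated correlation and limma's fry. Alternatives chosen after seeing the data were an offset that removes a smooth trend on gene length per library (lowess span 0.3), leaving out both libraries with the most Rn45s, and leaving out Y-linked genes and Xist. Without both libraries with the most Rn45s, AAV-GFP and AAV-XBP1S hold 1 library each. All spread then comes from the AAV-ATF6N libraries, so calls in that setting on genes and lists are not replicated.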

Results

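RNA was sequenced from cardiomyocytes of wild-type mice that had received an adeno-associated virus (AAV) at postnatal day 1. The cells were isolated at 4 weeks of age by Langendorff perfusion, which digests the heart through its own vessels, and purified by fluorescence-activated sorting. The virus carried GFP as control, XBP1S or ATF6N. XBP1S is the usual name of the spliced, active form of XBP1, and ATF6N that of the amino-terminal, nuclear fragment of ATF6. Both are transcription factors of the unfolded protein response, the program that endoplasmic reticulum (ER) stress turns on. There were 3 groups of 2 libraries, and the comparisons ask what each factor changes in the transcriptome of heart muscle cells and where the factors differ. The table held 23337 genes. Total counts were 112049342 and 72855725 in the AAV-GFP libraries, 85298584 and 71571677 in AAV-XBP1S, and 83930718 and 67702482 in AAV-ATF6N, and 14587 genes passed the filter on low counts. The labels do not say that the replicates came from separate animals. The p-values on single genes therefore measure only the spread between these samples, which may be technical. Those of lists, from camera with a preset correlation, compare the list's genes with all other genes. They treat genes as the units, so they do not measure how far libraries of a group vary. AAV-GFP replicate 1 stood apart on the leading principal component (43.9% of the variance), and 0.337% of its counts fell on Rn45s, the ribosomal RNA precursor, against 0.0319% to 0.130% in the other 5. Values below are means ± SD in CPM, counts scaled to the library size, over the 2 libraries of a group, with positions on mm10, and log2 fold changes carry the standard error (SE) of the fit. All calls on single genes rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

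The delivered genes were both higher in the libraries named after them, but neither passed the test as run here on all 6 libraries. Xbp1 (chromosome 11, 5520967 to 5525872) stood at 107 ± 12.2 CPM in AAV-GFP, 163 ± 3.94 CPM in AAV-XBP1S and 148 ± 4.76 CPM in AAV-ATF6N. The log2 fold change over AAV-GFP was 0.61 (SE 0.19) in AAV-XBP1S and 0.47 (SE 0.19) in AAV-ATF6N, with edgeR adjusted p-values of 0.307 and 0.358. Atf6 (chromosome 1, 170704457 to 170867771) stood at 57.7 ± 18.1, 94.0 ± 24.0 and 160 ± 2.98 CPM in the same order. Its log2 fold change was 1.47 (SE 0.29) in AAV-ATF6N and 0.70 (SE 0.29) in AAV-XBP1S, with edgeR adjusted p-values of 0.126 and 0.425. The authors' deposited table gives Atf6 in AAV-ATF6N a log2 fold change of 1.48 with an adjusted p of 0.000799, below 0.05, while Xbp1 in AAV-XBP1S has an adjusted p of 0.829 there. Here Atf6 passed in AAV-ATF6N with DESeq2 (adjusted p = 0.000487) and without a filter on low counts (edgeR, 0.00815). It also passed with a gene-length offset, chosen after seeing the data (log2 fold change 1.14, edgeR adjusted p = 0.0432). Without AAV-GFP replicate 2, which leaves 1 control library, its log2 fold change was 1.83. Leaving out both libraries with the most Rn45s, also chosen after seeing the data, leaves AAV-GFP and AAV-XBP1S with 1 library each. Atf6 then had 1.18 in AAV-ATF6N and 0.65 in AAV-XBP1S, and Xbp1 0.53 in AAV-XBP1S and 0.36 in AAV-ATF6N. All spread comes from the AAV-ATF6N libraries there, so no p-value is given. In both genes each treated library lay above both AAV-GFP libraries. Counts per gene add spliced to unspliced transcripts, and viral transcripts enter them only where their sequence maps to the mouse gene.

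**Figure D1:**
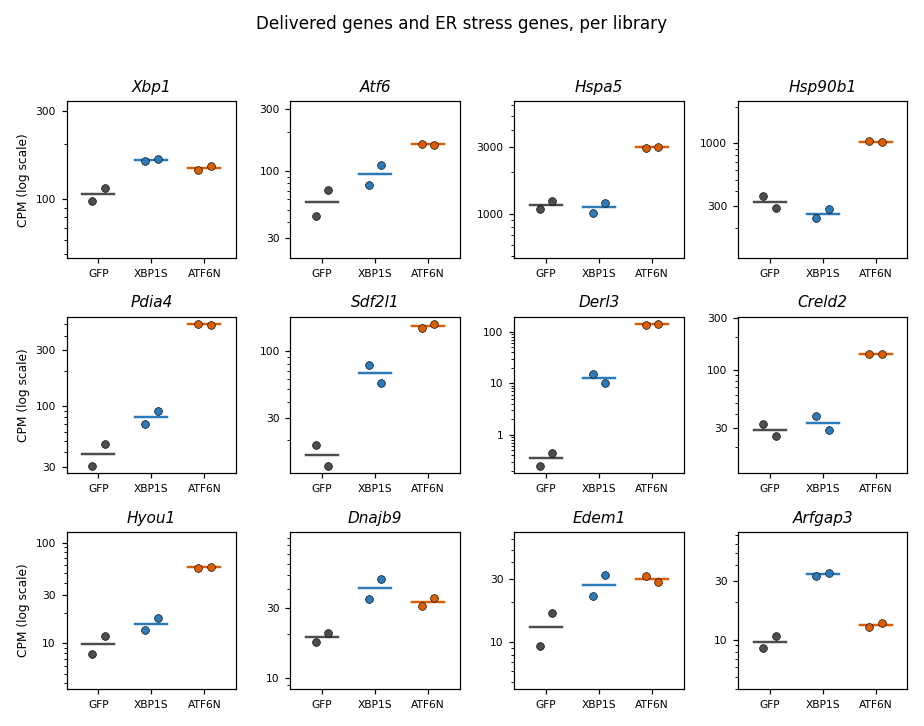
CPM on a log scale of the delivered genes and 10 ER stress genes in each of the 6 libraries (points), with a line at each group's mean. Pdia4 stood at 502 CPM on average in AAV-ATF6N against 79.8 in AAV-XBP1S and 38.4 in AAV-GFP, whereas Arfgap3 was highest in AAV-XBP1S (33.8 CPM).

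In AAV-XBP1S against AAV-GFP, 26 genes rose and 20 fell. The highest gains by p-value included Tnni1, the slow skeletal troponin I of the fetal heart, at 97.2 ± 26.5 against 1.86 ± 0.0953 CPM (52.1-fold; chromosome 1, 135799421 to 135810989). Derl3, a component of ER-associated degradation, rose 36.5-fold from 0.346 ± 0.145 to 12.5 ± 3.21 CPM (chromosome 10, 75893398 to 75895941). Sdf2l1, an ER chaperone cofactor, rose 4.40-fold to 66.9 ± 14.9 CPM, and Arfgap3, which acts in Golgi vesicle transport, rose 3.50-fold to 33.8 ± 1.5 CPM. Their log2 fold changes were 5.70 (SE 0.29), 5.19 (SE 0.37), 2.14 (SE 0.28) and 1.81 (SE 0.22), with edgeR adjusted p-values of 0.00265, 0.00551, 0.0447 and 0.0371. Also higher were Pyroxd2 (21.2-fold), Cd24a (9.81-fold), Tnfrsf23 (16.7-fold), Mtap1a (9.09-fold), the neuronal tubulin Tubb3 (14.9 ± 0.00483 against 0.0305 ± 0.0431 CPM, a log2 fold change of 8.70) and the epithelial keratin Krt18 (8.88-fold). Without AAV-GFP replicate 1 the remaining control library held no Tubb3 count. The log2 fold change of 13.19 fitted there is therefore not a measured size. The inducible heat shock protein genes Hspa1b and Hspa1a rose 4.23-fold and 3.95-fold, and the histocompatibility gene H2-Q6 7.26-fold. Hspa1a and Hspa1b are near-identical, and H2-Q6 belongs to a family of close copies, so reads can be shared among them and their single values are uncertain. Without AAV-XBP1S replicate 1, or without replicate 2, 2 of the 46 calls remained (Tnni1 and Eif2s3y), without AAV-ATF6N replicate 1 or 2 there remained 15 and 14, and without AAV-GFP replicate 1 there remained 40 among 72 calls. Without AAV-GFP replicate 2 all 46 remained among 242 calls.

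Among the genes that fell in AAV-XBP1S, Icam1, a leukocyte adhesion molecule (chromosome 9, 21015960 to 21028796), fell 18.9-fold from 369 ± 64.8 to 19.5 ± 1.07 CPM, Selp, the adhesion molecule P-selectin, 15.2-fold to 0.561 ± 0.0186 CPM, the cytokine gene Il15 8.03-fold to 3.77 ± 0.0430 CPM and the interferon regulatory factor gene Irf1 4.43-fold to 47.9 ± 1.69 CPM. Their log2 fold changes were -4.24 (SE 0.24), -3.92 (SE 0.35), -3.01 (SE 0.26) and -2.15 (SE 0.20), with edgeR adjusted p-values of 0.00355, 0.0137, 0.0137 and 0.0155. Rnd1, a small GTPase, fell 13.2-fold, Gadd45b 6.99-fold, Nuak2 6.94-fold and Zbtb16 4.18-fold. The Y-linked genes Eif2s3y and Ddx3y fell as well. Eif2s3y had no count in AAV-XBP1S against 15.1 ± 1.99 CPM in AAV-GFP, at least 896-fold lower with a floor of 3 counts over the group, and Ddx3y had 2 counts in AAV-XBP1S against 2640 in AAV-GFP.

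Most of the classical ER stress genes fixed in advance did not pass in this comparison. The major ER chaperone gene Hspa5 stood at 1111 ± 132 against 1152 ± 106 CPM (log2 fold change -0.05, SE 0.19), and Hsp90b1 at -0.32 (SE 0.20). Dnajb9, Edem1, Pdia4 and Manf had log2 fold changes of 1.11 (SE 0.23), 1.06 (SE 0.33), 1.06 (SE 0.26) and 1.13 (SE 0.37), with edgeR adjusted p-values of 0.167, 0.309, 0.232 and 0.336. Hyou1, Creld2, Sec61b and Herpud1 had 0.67 (SE 0.27), 0.22 (SE 0.23), -0.02 (SE 0.39) and -0.38 (SE 0.18). The stress genes Ddit3, Atf4 and Trib3 had -0.74 (SE 0.28), -0.20 (SE 0.31) and 0.26 (SE 0.23). Gfpt1, of the hexosamine pathway, had 0.43 (SE 0.33) and the catalase gene Cat -0.37 (SE 0.22). Among cardiac genes, the natriuretic peptide genes Nppa and Nppb had 1.21 (SE 0.41) and 0.96 (SE 0.34), skeletal actin Acta1 0.62 (SE 0.19), the myosins Myh6 and Myh7 0.14 (SE 0.34) and -0.02 (SE 0.27), and the calcium handling genes Atp2a2 and Ryr2 -0.61 (SE 0.37) and -0.12 (SE 0.31). In none of these did edgeR's adjusted p pass 0.05. Pdia4 passed without AAV-GFP replicate 2 (1.43, edgeR adjusted p = 0.0486).

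As groups, the targets that XBP1s is known to prefer rose in AAV-XBP1S, with a median log2 fold change of 0.44 over 30 members and 25 of them above 0 (camera adjusted p = 4.39e-06). Of these members 1 rose by the test over all genes, Arfgap3, and 3 when adjusted over the list alone, the others being the retrieval receptor gene Kdelr3 (1.78, SE 0.24) and Dnajb9. With an estimated correlation the adjusted p was 0.169. The ER chaperones and oxidoreductases (median 0.34, 35 members, 1 higher and 2 adjusted over the list alone) and the ER to Golgi transport genes (median 0.25, 44 members, 1 higher and 2 adjusted over the list alone) rose too, both with a camera adjusted p of 0.00328. The adjusted p with an estimated correlation was 0.178 for both. The hexosamine list was called higher with a median of 0.34 over 8 members, 7 of them above 0 (camera adjusted p = 0.0202), with none past the test over all genes and 2 adjusted over the list alone, among them Pgm3 (1.00, SE 0.29). Their adjusted p was 0.389 with an estimated correlation. The targets that ATF6 is known to prefer were not called (median 0.12, mean 0.53, camera adjusted p = 0.0669), although Derl3 and Sdf2l1 are among their 19 members. They were called higher with fry (adjusted p = 0.00114) and with a gene-length offset chosen after seeing the data (0.0212). Without AAV-GFP replicate 2 the chaperone list no longer passed (adjusted p = 0.101), nor without AAV-GFP replicate 1 the transport list (0.0773), and the hexosamine list failed without AAV-GFP replicate 1 (0.107), AAV-GFP replicate 2 (0.0525) or AAV-XBP1S replicate 2 (0.191), or with fry in place of camera (0.0563). Of the medians, the XBP1s list had 0.70 without AAV-GFP replicate 2, the transport list 0.13 without AAV-GFP replicate 1, and the hexosamine list 0.67 without AAV-GFP replicate 2 or AAV-XBP1S replicate 1 and 0.13 without AAV-XBP1S replicate 2.

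Cell cycle genes rose in AAV-XBP1S more than any other list, with a median log2 fold change of 1.77 over 30 members, 27 of them above 0 (camera adjusted p = 3.96e-17). Of these, 3 rose over all genes and 23 adjusted over the list alone. Ccna2 went from 0.331 ± 0.00817 to 3.70 ± 1.01 CPM and Mki67, a proliferation marker, from 0.803 ± 0.173 to 5.71 ± 1.90 CPM. Birc5 rose 10.2-fold, and Ccnb2 had a log2 fold change of 3.63 (SE 0.50) without passing over all genes. The adjusted p of the list was 0.0698 with an estimated correlation. Markers of other cell types rose in the same libraries: extracellular matrix (median 0.77, adjusted p = 1.56e-08), fibroblasts (0.75, 0.000205), endothelium (0.46, 0.00328), epicardium and Schwann cells (0.45, 0.00324) and smooth muscle and pericytes (0.41, 0.0242). Each of these 5 had an adjusted p of 0.178 with an estimated correlation. Among their members only Krt18, of the epicardial list, rose over all genes. Adjusted over the list alone, 3 of 30 matrix genes rose (Fbn1 at 1.16, SE 0.24, Lum and Hspg2), 4 of 16 fibroblast genes rose (Serping1, Lum and Dcn among them) and 1 fell (Fbln1, -1.03, SE 0.19), 2 of 12 epicardial genes rose (Krt18 and Krt8), and none of 16 endothelial or 12 smooth muscle genes did. The endothelial gene Cdh5 had 0.71 (SE 0.21) and the pericyte gene Rgs5 0.56 (SE 0.19). The erythroid markers fell (median -0.93 over 5 members, camera adjusted p = 0.0202, none over all genes and 1, Alas2, adjusted over the list alone), with an adjusted p of 0.178 with an estimated correlation. The smooth muscle list no longer passed without AAV-GFP replicate 2 (0.189) or AAV-XBP1S replicate 1 (0.112), nor the erythroid list without AAV-GFP replicate 1 (0.0773), AAV-GFP replicate 2 (0.0980) or AAV-XBP1S replicate 1 (0.128), with fry (0.0532), or without both libraries with the most Rn45s (0.113). Without AAV-GFP replicate 1 the median was 0.46 for the extracellular matrix, 0.86 for the epicardial list and -0.56 for the erythroid list. The erythroid median was -0.30 without AAV-XBP1S replicate 1 and -0.35 without both libraries with the most Rn45s.

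Lists of energy metabolism and contraction were called lower in AAV-XBP1S. Fatty acid uptake and oxidation had a median of -0.61 over 33 members, 31 of them below 0 (camera adjusted p = 4.14e-12), with 0 lower over all genes and 11 adjusted over the list alone. Examples were the uncoupling protein Ucp3 (-1.31, SE 0.26), Ech1 (-1.16, SE 0.25) and the regulator Ppara (-1.03, SE 0.22). The adjusted p was 0.169 with an estimated correlation. Calcium handling, T-tubule and ion channel genes had a median of -0.35 (camera adjusted p = 0.000347; 2 of 30 lower adjusted over the list alone, among them Jph2 at -1.05, SE 0.18) and sarcomere genes -0.38 (0.00175; none adjusted over the list alone, with Tcap at -1.61, SE 0.34). With an estimated correlation their adjusted p was 0.169 and 0.178. Oxidative phosphorylation had a median of -0.50 over 56 members (camera adjusted p = 1.63e-06) and the proteasome -0.28 over 31 (0.00175), and no member passed in either, nor when adjusted over the list alone. These adjusted p, with an estimated correlation, were 0.512 and 0.523. Glycolysis and glucose uptake (median -0.28, adjusted p = 0.0121) and the tricarboxylic acid cycle (-0.21, 0.0208) fell with no member past the test, and none adjusted over the list alone. With an estimated correlation their adjusted p was 0.181 and 0.178. The fetal and hypertrophic stress program rose (median 0.26 over 24 members, camera adjusted p = 0.0110), with Tnni1 past the test over all genes and Ankrd1 (0.80, SE 0.18) added when adjusted over the list alone. Its adjusted p was 0.178 with an estimated correlation. Without AAV-GFP replicate 1, oxidative phosphorylation (median 0.04, adjusted p = 0.499) and the proteasome (-0.01, 0.476) did not pass, nor did either with fry (0.352 for both). The proteasome also failed without AAV-XBP1S replicate 2 (0.153), glycolysis without AAV-GFP replicate 2 (0.178) or AAV-XBP1S replicate 2 (0.0638), the tricarboxylic acid cycle without AAV-GFP replicate 2 (0.279) or AAV-XBP1S replicate 2 (0.0638), and the stress program without AAV-GFP replicate 2 (0.0972). The median of oxidative phosphorylation was -0.88 without AAV-GFP replicate 2, -0.79 without AAV-XBP1S replicate 1, -0.25 without AAV-XBP1S replicate 2, -0.22 with the gene-length offset and -0.26 without both libraries with the most Rn45s. That of the proteasome was -0.44 without AAV-GFP replicate 2, -0.14 without AAV-XBP1S replicate 2, -0.13 with the offset and -0.18 without both. The sarcomere had -0.24 without AAV-GFP replicate 1, glycolysis -0.11 without AAV-XBP1S replicate 2, and the stress program 0.55 without AAV-GFP replicate 1, 0.44 without AAV-GFP replicate 2 and 0.45 without both.

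In this comparison 19 of 33 lists were called, and 14 were not. Medians of lists that were not called were 0.05 for ER-associated degradation (where Derl3 rose), 0.16 for ER translocation, signal peptidase and N-glycosylation, 0.34 for the interferon response, 0.57 for macrophages and leukocytes, 0.48 for atrial markers, 0.24 for sterol and fatty acid synthesis, -0.23 for phospholipid synthesis, -0.13 for NRF2 and antioxidant genes, -0.15 for lysosome and autophagy, -0.05 for p53 and apoptosis, and -0.23 for cytosolic heat shock, where Hspa1a and Hspa1b rose. For the PERK, ATF4 and CHOP stress response and the immediate early genes the median (0.00 and 0.06) and mean (0.07 and 0.13) were not below 0 while both tests pointed down. Camera adjusted p ran from 0.0542 to 0.979 over these 13 lists. Without AAV-GFP replicate 1 the translocation (adjusted p = 0.0135), interferon (0.0293) and atrial (0.0365) lists were called higher and phospholipid synthesis lower (0.0149). Without AAV-XBP1S replicate 2 the translocation (0.0148), interferon (0.0365), leukocyte (0.00899) and atrial (0.0479) lists were called higher. With the gene-length offset the translocation (0.000556), interferon (0.0212), leukocyte (0.00573) and atrial (0.0450) lists were called higher and phospholipid synthesis lower (0.0212). Without both libraries with the most Rn45s the translocation (0.00935) and interferon (0.0287) lists were called higher, and phospholipid synthesis (0.0124) and lysosome and autophagy (0.0129) lower. The 46 called genes compare with 1689 at an unadjusted p below 0.05 by edgeR, and the authors' deposited table lists 129 genes higher and 80 lower, with all 46 among them.

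**Figure D2:**
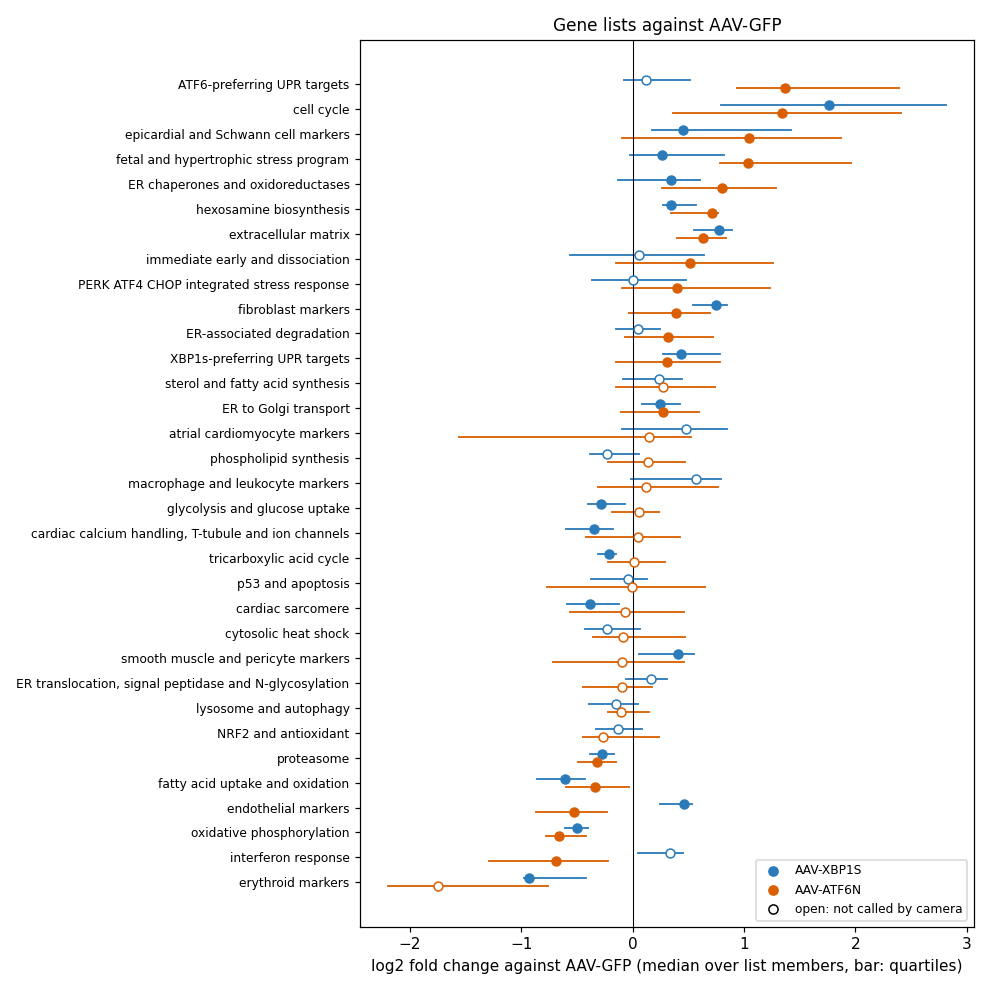
Median log2 fold change against AAV-GFP over the members of each of the 33 gene lists (points; bars span the quartiles), in AAV-XBP1S and AAV-ATF6N, with filled points for lists called by camera with a preset correlation and open points for lists not called. Targets preferred by ATF6 lay at 1.37 in AAV-ATF6N and 0.12 in AAV-XBP1S, and endothelial markers at -0.53 and 0.46.

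In AAV-ATF6N against AAV-GFP, 51 genes rose and 24 fell, with ER chaperone genes and fetal cardiac genes prominent among the gains. Derl3 rose 407-fold to 139 ± 4.88 CPM, Pdia4, an ER protein disulfide isomerase (chromosome 6, 47796141 to 47813512), 13.1-fold from 38.4 ± 11.6 to 502 ± 6.76 CPM, Sdf2l1 10.5-fold to 160 ± 8.74 CPM, and Hyou1, Creld2, Hsp90b1 and Hspa5 5.78-fold, 4.94-fold, 3.13-fold and 2.59-fold. Hspa5 (chromosome 2, 34772090 to 34776529) reached 2986 ± 64.0 CPM against 1152 ± 106 CPM. The log2 fold changes of these 7 genes were 8.67 (SE 0.43), 3.71 (SE 0.29), 3.39 (SE 0.29), 2.53 (SE 0.29), 2.30 (SE 0.25), 1.65 (SE 0.21) and 1.37 (SE 0.19), with edgeR adjusted p-values of 0.00130, 0.00716, 0.00989, 0.0277, 0.0248, 0.0357 and 0.0462. Pdia2, another disulfide isomerase gene, had no count in AAV-GFP and 33.6 ± 0.836 CPM in AAV-ATF6N, at least 1910-fold higher with a floor of 3 counts over the group. Of the fixed ER genes, Manf (2.26, SE 0.39), Herpud1 (0.72, SE 0.18), Dnajb9 (0.80, SE 0.23), Edem1 (1.2, SE 0.33) and Sec61b (-1.0, SE 0.40) did not pass, with edgeR adjusted p-values of 0.0876, 0.195, 0.270, 0.249 and 0.358. Nor did Ddit3 (0.63, SE 0.28), Atf4 (-0.11, SE 0.31), Trib3 (0.73, SE 0.23), Gfpt1 (0.74, SE 0.33) or Cat (0.70, SE 0.22), the last at an edgeR adjusted p of 0.304. Without AAV-ATF6N replicate 1, or without replicate 2, 4 of the 75 calls remained (Tnni1, Pdia2, Derl3 and Slc2a6), without AAV-XBP1S replicate 1 or 2 there remained 8, and without AAV-GFP replicate 1 there remained 60, with Hspa5 no longer among them. Without AAV-GFP replicate 2 all 75 remained among 3052 calls. Among the fixed genes above, Manf passed by edgeR without AAV-GFP replicate 1 (2.89, adjusted p = 0.0285). Without AAV-GFP replicate 2, Manf (1.82, 0.0287), Edem1 (1.67, 0.0325), Sec61b (-1.47, 0.0318), Herpud1 (0.72, 0.0385) and Cat (0.97, 0.0329) did.

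Among cardiac genes, Tnni1 rose 138-fold to 257 ± 12.7 CPM, Nppa, encoding atrial natriuretic peptide (chromosome 4, 148000746 to 148002067), 13.7-fold from 165 ± 90.6 to 2262 ± 110 CPM, Casq1, the skeletal calsequestrin, 6.30-fold to 139 ± 2.62 CPM, and Acta1, skeletal actin, 5.23-fold to 629 ± 10.2 CPM. Their log2 fold changes were 7.11 (SE 0.31), 3.78 (SE 0.45), 2.66 (SE 0.21) and 2.39 (SE 0.20), with edgeR adjusted p-values of 0.00130, 0.0298, 0.00713 and 0.00989. Nppb (1.95, SE 0.35), Myh7 (1.03, SE 0.27), Myh6 (1.04, SE 0.34), Atp2a2 (0.35, SE 0.37) and Ryr2 (0.12, SE 0.31) did not pass, with edgeR adjusted p-values of 0.0966, 0.228, 0.313, 0.612 and 0.848. Nppb passed without AAV-GFP replicate 1 (2.42, edgeR adjusted p = 0.0449) or replicate 2 (1.6, 0.0325), and Myh6 without AAV-GFP replicate 2 (1.52, 0.0363). Also higher were the sugar transporter family gene Slc2a6 (66.0-fold), the kinase genes Prkcz (21.5-fold), Pak3 (20.9-fold) and Pdk3 (4.62-fold), the last an inhibitory kinase of pyruvate dehydrogenase, and the mitotic gene Ube2c (9.01-fold). Lower were Icam1 (12.5-fold, to 29.5 ± 3.17 CPM), Selp (18.4-fold), Il15 (13.7-fold), Rnd1 (11.7-fold), Irf1 (7.80-fold), H2-K2 (6.09-fold), Adh1 (4.20-fold), the NF-kB cofactor Bcl3 (3.74-fold) and the interferon-induced GTPase Tgtp1 (3.61-fold). H2-K2 and Tgtp1 have close copies with which reads can be shared. Xist, the RNA of the inactive X chromosome, was lower at 0.145 ± 0.0745 against 16.3 ± 11.8 CPM.

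**Figure D3:**
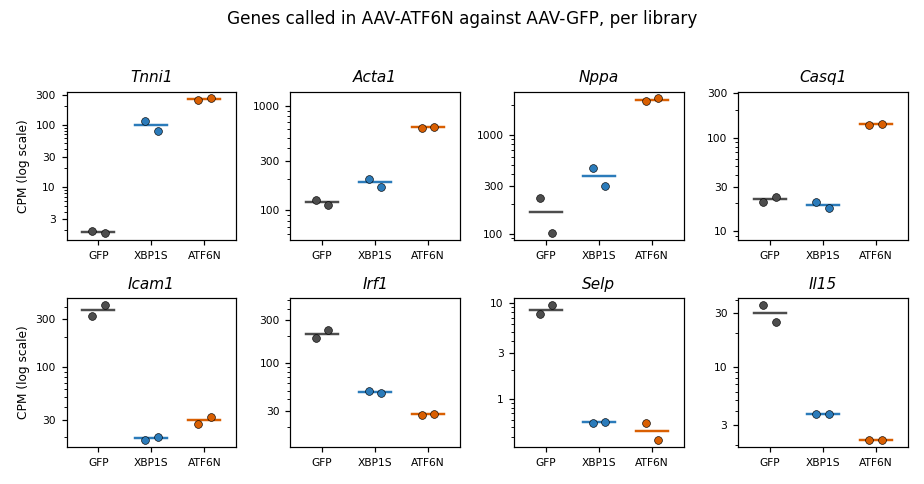
CPM on a log scale of 4 fetal or skeletal muscle genes (top) and 4 genes called lower in both treated groups (bottom) in each of the 6 libraries (points), with a line at each group's mean. Icam1 lay at 369 CPM on average in AAV-GFP against 19.5 in AAV-XBP1S and 29.5 in AAV-ATF6N.

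The targets preferred by ATF6 rose in AAV-ATF6N with a median log2 fold change of 1.37 over 19 members, 18 of them above 0 (camera adjusted p = 2.53e-15). Of these, 8 rose over all genes and 17 adjusted over the list alone. The adjusted p was 0.0529 with an estimated correlation. The ER chaperones and oxidoreductases, which share 11 members with that list, rose with a median of 0.80 (camera adjusted p = 4.87e-09; 6 of 35 higher over all genes; 18 higher and 1 lower adjusted over the list alone), and their adjusted p was 0.0699 with an estimated correlation. The PERK, ATF4 and CHOP stress response had a median of 0.40 (0.00105), with the stress factor Atf3 higher over all genes (1.34, SE 0.19), and 7 members higher and 1 lower adjusted over the list alone, among the former Phgdh (3.21, SE 0.47), Nupr1 (2.58, SE 0.39) and Gdf15 (2.01, SE 0.33). ER-associated degradation had 0.32 (0.00625), with Derl3 past the test, and Sel1l (2.49, SE 0.47), Syvn1 (1.37, SE 0.31) and Herpud1 added when adjusted over the list alone. With an estimated correlation their adjusted p was 0.154 and 0.171. The hexosamine list was called higher with a median of 0.71, 7 of 8 members above 0 (0.00625; none over all genes and 1, Gfpt2 at 1.32, SE 0.23, adjusted over the list alone), with an adjusted p of 0.407 with an estimated correlation. The targets preferred by XBP1s (0.31, 0.0306; 1 adjusted over the list alone, Dnajc3 at 1.38, SE 0.22) and ER to Golgi transport (0.27, 0.0244; none adjusted over the list alone, with Sec24a at 1.17, SE 0.22) rose, with an adjusted p of 0.290 with an estimated correlation for both. The XBP1s list failed without AAV-GFP replicate 2 (adjusted p = 0.175) or AAV-ATF6N replicate 2 (0.0829), the transport list without AAV-GFP replicate 1 (0.113) or AAV-ATF6N replicate 2 (0.0520), and ER-associated degradation without AAV-GFP replicate 2 (0.0703). With fry the transport and hexosamine lists failed (0.0658 for both). Medians without AAV-GFP replicate 1 were 0.20 for the XBP1s list, 0.13 for transport and 0.38 for hexosamine, and they rounded to the same values without both libraries with the most Rn45s. Those without AAV-GFP replicate 2 were 0.47 for the XBP1s list, 0.42 for transport, 0.62 for the PERK, ATF4 and CHOP response and 0.48 for ER-associated degradation. With a gene-length offset, chosen after seeing the data, ER-associated degradation had 0.10 and hexosamine 0.45.

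The fetal and hypertrophic stress program rose with a median of 1.03 over 24 members, 22 of them above 0 (camera adjusted p = 1.1e-10). Over all genes 4 rose and 1 fell, and adjusted over the list alone 14 rose and 1 fell, the latter the atrial myosin light chain Myl7 (-5.72, SE 0.72). The adjusted p was 0.0529 with an estimated correlation. Cell cycle genes rose with a median of 1.34 over 30 members (1.1e-10; 3 over all genes and 16 adjusted over the list alone), with Top2a at 6.73 ± 0.942 against 0.331 ± 0.266 CPM, Ccna2 at 2.88 ± 0.138 against 0.331 ± 0.00817 CPM, Birc5 7.32-fold higher, and Mki67 at 2.41 (SE 0.36) without passing over all genes. Their adjusted p was 0.0529 with an estimated correlation. Immediate early and dissociation genes rose with a median of 0.51 (0.000756), with Fos (1.70, SE 0.19) and Egr1 (1.92, SE 0.25) past the test over all genes and 9 higher and 1 lower adjusted over the list alone. Their adjusted p was 0.289 with an estimated correlation, and the list failed without AAV-GFP replicate 2 (adjusted p = 0.0901).

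The interferon response fell in AAV-ATF6N, with a median of -0.69 over 24 members, 22 of them below 0 (camera adjusted p = 1.12e-06; 1, Isg15, over all genes and 11 adjusted over the list alone). Isg15 went from 14.1 to 3.03 CPM on average, Ifit1 had -1.28 (SE 0.22) and Rsad2 -1.10 (SE 0.22). The adjusted p was 0.165 with an estimated correlation. Endothelial markers fell with a median of -0.53 over 16 members (0.000166; 0 over all genes and 6 adjusted over the list alone, with Emcn at -1.05, SE 0.19, and Egfl7 at -1.2, SE 0.28), at an adjusted p of 0.143 with an estimated correlation. Fatty acid uptake and oxidation fell with a median of -0.34 (0.000532; none over all genes and 3, among them Ucp3 and Ech1, adjusted over the list alone), at an adjusted p of 0.208 with an estimated correlation. Oxidative phosphorylation (-0.66, 2.75e-06) and the proteasome (-0.32, 0.00664) fell with no member past the test, nor when adjusted over the list alone, and both had an adjusted p of 0.671 with an estimated correlation. Extracellular matrix (0.64, 7.59e-06; none adjusted over the list alone), fibroblast markers (0.39, 0.0190; 2, Col14a1 and Lamc3, adjusted over the list alone) and epicardial and Schwann cell markers (1.05, 0.00800; 2, Krt18 and Upk3b, adjusted over the list alone) rose, with adjusted p of 0.290, 0.294 and 0.201 with an estimated correlation. Without AAV-GFP replicate 1 oxidative phosphorylation had a median of -0.08 (adjusted p = 0.231) and the proteasome -0.04 (0.613), and the fibroblast list failed without AAV-GFP replicate 1 (0.0800) or replicate 2 (0.0820). These medians were -1.07 and -0.51 without AAV-GFP replicate 2. The extracellular matrix, still called in each case, had a median of 0.30 without AAV-GFP replicate 1, 0.96 without AAV-GFP replicate 2, 0.35 with the gene-length offset and 0.30 without both libraries with the most Rn45s. The fibroblast median was 0.15 without AAV-GFP replicate 1 and without both. Oxidative phosphorylation had -0.08 and the proteasome -0.03 without both. With a gene-length offset, chosen after seeing the data, oxidative phosphorylation also failed (median -0.08, adjusted p = 0.178), as did the proteasome (0.043, 0.580). Without both libraries with the most Rn45s, the proteasome (0.310) and fibroblast (0.0527) lists failed, and with fry oxidative phosphorylation (0.376), the proteasome (0.415) and the extracellular matrix (0.0658).

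In this comparison 18 of 33 lists were called. Medians of lists not called were -0.10 for ER translocation, -0.07 for the sarcomere, 0.05 for calcium handling, 0.06 for glycolysis, 0.01 for the tricarboxylic acid cycle, 0.28 for sterol and fatty acid synthesis, 0.14 for phospholipid synthesis, -0.27 for NRF2 and antioxidant genes, -0.11 for lysosome and autophagy, -0.10 for smooth muscle and pericytes and -1.75 for erythroid markers. For cytosolic heat shock, p53 and apoptosis, macrophages and leukocytes, and atrial markers the median (-0.08, -0.01, 0.12 and 0.15), the mean (0.05, 0.01, -0.31 and -0.71) and the direction of the test (up, down, up and down) did not share 1 sign throughout. Camera adjusted p ran from 0.0825 to 0.921 over these 15 lists. Sterol and fatty acid synthesis was called higher without AAV-GFP replicate 2 (0.0498), and the leukocyte list with the gene-length offset (0.0229). Within the atrial list Nppa rose and Myl7 fell over all genes, and within the erythroid list Alas2 fell. Adjusted over the list alone, 1 atrial gene rose and 4 fell. The atrial gene Sln stood at 0.163 ± 0.0137 CPM in AAV-ATF6N against 5.43 ± 4.39 CPM in AAV-GFP. Whether the libraries differ in atrial cells was not tested. The 75 called genes compare with 1963 at an unadjusted p below 0.05 by edgeR, and the authors' deposited table lists 272 genes higher and 144 lower, with all 75 among them.

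Compared directly, 25 genes were higher in AAV-ATF6N than in AAV-XBP1S and 8 were lower. Lower genes outnumbered higher ones in several alternatives: 278 were higher and 391 lower without AAV-GFP replicate 1, 234 and 411 without AAV-GFP replicate 2, 275 and 391 with only the groups compared, 175 and 283 without a filter on low counts, 321 and 518 with DESeq2, and 257 and 349 with the gene-length offset. Without both libraries with the most Rn45s, which leaves AAV-XBP1S with 1 library, higher genes outnumbered lower ones. Derl3, Pdia4, Creld2 and Hsp90b1 were 11.2-fold, 6.30-fold, 4.25-fold and 3.91-fold higher in AAV-ATF6N, Acta1 3.39-fold, Casq1 7.26-fold and Pdia2 10.9-fold, with log2 fold changes of 3.48 (SE 0.33), 2.66 (SE 0.28), 2.09 (SE 0.24), 1.97 (SE 0.21), 1.76 (SE 0.20), 2.86 (SE 0.21) and 3.45 (SE 0.24). The edgeR adjusted p-values were 0.0225, 0.0337, 0.0415, 0.0337, 0.0399, 0.00731 and 0.0154. Hspa5 was at 2986 ± 64.0 against 1111 ± 132 CPM (1.43, SE 0.19), Nppa at 2.56 (SE 0.42), Hyou1 at 1.86 (SE 0.28), Herpud1 at 1.10 (SE 0.18) and Sdf2l1 at 1.25 (SE 0.27) without passing, at edgeR adjusted p-values of 0.0579, 0.0684, 0.0590, 0.0655 and 0.111. Prkcz was 24.4-fold and Pak3 16.5-fold higher in AAV-ATF6N. Lower there were Pyroxd2 (24.3-fold), the metallothionein Mt3 (16.7-fold), Ptplad2 (6.35-fold), Tnfrsf23 (6.89-fold) and Myl7, at 0.363 ± 0.0797 against 34.6 ± 14.5 CPM. Manf (1.12, SE 0.37), Dnajb9 (-0.31, SE 0.23), Edem1 (0.14, SE 0.33), Sec61b (-0.98, SE 0.40), Ddit3 (1.37, SE 0.29), Atf4 (0.08, SE 0.31), Trib3 (0.47, SE 0.23), Gfpt1 (0.32, SE 0.33), Cat (1.07, SE 0.23), Nppb (0.99, SE 0.34), Myh6 (0.90, SE 0.34), Myh7 (1.05, SE 0.27), Atp2a2 (0.96, SE 0.37) and Ryr2 (0.24, SE 0.31) did not pass by edgeR. Neither did the delivered genes Xbp1 (-0.14, SE 0.19) and Atf6 (0.76, SE 0.29). Without both libraries with the most Rn45s, which leaves AAV-XBP1S with 1 library, they had -0.16 and 0.53. The calls compare with 1932 genes at an unadjusted p below 0.05, and 33 of 33 remained without either AAV-GFP library. Without either one Hspa5, Nppa, Hyou1, Herpud1, Sdf2l1, Manf, Ddit3 and Cat also passed by edgeR. Without AAV-XBP1S replicate 1 or 2 only Eif2s3y remained, and without AAV-ATF6N replicate 1 or 2 only Eif2s3y, Ddx3y and Kdm5d.

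The lists set the AAV-ATF6N and AAV-XBP1S libraries apart in the ER, in a comparison where sex-linked genes differ as well (below). Targets preferred by ATF6 were higher in AAV-ATF6N than in AAV-XBP1S (median 1.25, 4 over all genes and 17 of 19 adjusted over the list alone, camera adjusted p = 7.92e-15), and targets preferred by XBP1s were lower (median -0.25, none over all genes, 3 lower and 1 higher adjusted over the list alone, 0.0271). Of the latter, Kdelr3 had -1.55 (SE 0.24), Arfgap3 -1.36 (SE 0.22) and Edem2 -0.84 (SE 0.22), with Dnajc3 at 0.98 (SE 0.21). These adjusted p, with an estimated correlation, were 0.0982 and 0.199. ER chaperones (0.54, 7.19e-05; 3 over all genes; 14 higher and 2 lower adjusted over the list alone), the PERK, ATF4 and CHOP response (0.47, 0.000100; 6 adjusted over the list alone, among them Gdf15, Cebpb at 1.88, SE 0.27, and Ddit4 at 1.33, SE 0.20) and ER-associated degradation (0.26, 0.00738; 1 over all genes; 4 higher and 1 lower adjusted over the list alone) were higher in AAV-ATF6N, and ER translocation, signal peptidase and N-glycosylation was lower (-0.25, 0.0152; none adjusted over the list alone, with Ssr2 at -0.75, SE 0.25). Their adjusted p were 0.107, 0.107, 0.158 and 0.158 with an estimated correlation. The XBP1s list failed without AAV-XBP1S replicate 2 (adjusted p = 0.245) or AAV-ATF6N replicate 1 (0.0907), and the translocation list without AAV-ATF6N replicate 1 (0.0600). With fry the XBP1s list failed (0.065). The XBP1s list had a median of -0.40 without AAV-XBP1S replicate 1. That of ER-associated degradation was 0.11 without AAV-XBP1S replicate 1, 0.10 with the gene-length offset and 0.15 without both libraries with the most Rn45s, where the translocation list had -0.16.

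Outside the ER, the fetal and hypertrophic stress program was higher in AAV-ATF6N than in AAV-XBP1S (median 0.97, camera adjusted p = 7.51e-07; 1 higher and 1 lower over all genes; 12 higher, with Rcan1 at 1.24, SE 0.18, and 1 lower adjusted over the list alone). Calcium handling genes (0.43, 0.000581; none adjusted over the list alone) and the sarcomere (0.29, 0.00738; none adjusted over the list alone, with Myom1 at 0.66, SE 0.21) were higher as well. These adjusted p were 0.105, 0.107 and 0.199 with an estimated correlation. Fatty acid uptake and oxidation (0.19, 0.00211; 3 adjusted over the list alone, Ppargc1a at 1.25, SE 0.21, Ppara at 1.07, SE 0.22, and Pdk4 at 1.70, SE 0.36), glycolysis (0.25, 0.00294; 2, Hk2 and Pfkfb2, adjusted over the list alone), the tricarboxylic acid cycle (0.18, 0.0235; none adjusted over the list alone) and phospholipid synthesis (0.17, 0.0112; none adjusted over the list alone) were higher. With an estimated correlation the adjusted p was 0.174 for the first-named 3 and 0.189 for phospholipid synthesis. Immediate early genes were higher (0.50, 0.000173; 1, Myc, over all genes; 7 higher and 1 lower adjusted over the list alone), with an adjusted p of 0.174 with an estimated correlation. Lower in AAV-ATF6N were the interferon response (-1.03, 4.21e-11; 16 of 24 adjusted over the list alone, with Oasl2 at -1.60, SE 0.23), endothelial markers (-0.94, 3.29e-09; 13 of 16, with Emcn at -1.54, SE 0.20, adjusted over the list alone), smooth muscle and pericyte markers (-0.41, 0.0143; 3, with Kcnj8 at -1.58, SE 0.23, adjusted over the list alone) and the cell cycle (-0.42, 0.00738; none adjusted over the list alone), none of them with a member past the test over all genes. Their adjusted p were 0.107, 0.105, 0.174 and 0.158 with an estimated correlation. Without AAV-XBP1S replicate 2 the sarcomere (adjusted p = 0.169), cell cycle (0.0739), fatty acid (0.0702), glycolysis (0.0788), phospholipid (0.0670) and tricarboxylic acid cycle (0.185) lists failed, the last also without AAV-ATF6N replicate 2 (0.0843). With fry the sarcomere list failed (0.15). With the gene-length offset the medians were 0.29 for the fatty acid list and 0.30 for the tricarboxylic acid cycle, and without both libraries with the most Rn45s 0.29 for the fatty acid list and 0.28 for phospholipid synthesis.

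Of the 33 lists 15 were not called between AAV-ATF6N and AAV-XBP1S, with camera adjusted p from 0.0658 to 0.970. Their medians were -0.03 for ER to Golgi transport, 0.21 for hexosamine biosynthesis, -0.15 for oxidative phosphorylation, 0.14 for cytosolic heat shock, -0.17 for NRF2 and antioxidant genes, 0.08 for lysosome and autophagy, 0.10 for p53 and apoptosis, -0.23 for extracellular matrix, -0.26 for macrophages and leukocytes, -0.78 for erythroid markers and -0.47 for epicardial and Schwann cell markers. Sterol synthesis, the proteasome, fibroblast markers and atrial markers had medians of -0.04, 0.01, -0.39 and 0.09, means of -0.00, -0.02, 0.07 and -1.11, and tests pointing up, up, down and down, so that these did not share 1 sign. Oxidative phosphorylation was called higher without AAV-XBP1S replicate 1 (median 0.15, adjusted p = 0.0355) and lower without AAV-XBP1S replicate 2 (-0.42, 0.0280), where the leukocyte list was called lower too (0.0229). With the gene-length offset oxidative phosphorylation (0.000151) and the proteasome (0.00169) were called higher and the extracellular matrix lower (0.0339). Without both libraries with the most Rn45s oxidative phosphorylation (4.64e-05), the proteasome (0.0101) and cytosolic heat shock (0.0424) were called higher, and the extracellular matrix (0.0111) and fibroblast markers (0.0451) lower.

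Sex-linked genes separated the groups. Eif2s3y, Ddx3y and Kdm5d, all on the Y chromosome, stood at 43.8 ± 0.751, 91.8 ± 3.05 and 12.8 ± 2.37 CPM in AAV-ATF6N and at 15.1 ± 1.99, 16.3 ± 6.65 and 2.31 ± 0.211 CPM in AAV-GFP, while the AAV-XBP1S libraries held 2 counts of Ddx3y and none of the others. Eif2s3y was at least 2550-fold and Kdm5d at least 758-fold higher in AAV-ATF6N than in AAV-XBP1S, with a floor of 3 counts over the group. Xist was the reverse, at 31.7 ± 16.2 CPM in AAV-XBP1S, 16.3 ± 11.8 CPM in AAV-GFP and 0.145 ± 0.0745 CPM in AAV-ATF6N. These genes account for 3 of the 20 lower calls in AAV-XBP1S, for 1 of 51 higher and 1 of 24 lower in AAV-ATF6N, and for 3 of 25 higher and 1 of 8 lower in the direct comparison. Leaving them out gave 26 higher and 17 lower, 50 and 23, and 22 and 7.

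**Figure D4:**
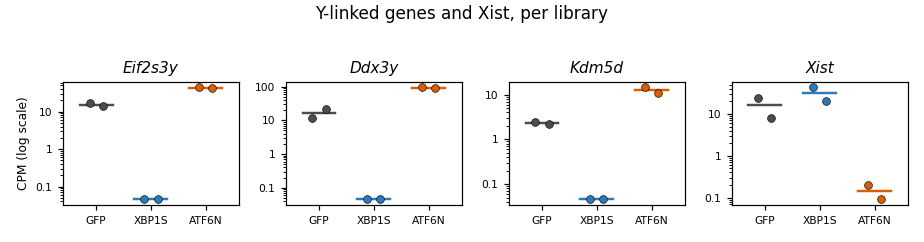
CPM on a log scale of Eif2s3y, Ddx3y, Kdm5d and Xist in each of the 6 libraries (points), with a line at each group's mean. Points and lines below 0.0459 CPM, the value of 3 counts in the shallowest library, are drawn at that value, as all Y-linked values of AAV-XBP1S are.

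Of the genes called against AAV-GFP, 12 were higher and 8 lower in both comparisons. Higher in both were Tnni1, Derl3, Slc2a6 (11.5-fold in AAV-XBP1S and 66.0-fold in AAV-ATF6N), Pdia2 (at least 174-fold and at least 1910-fold), Krt20 (at least 56.3-fold and at least 279-fold) and the mitotic spindle gene Spag5 (80.4-fold and 71.2-fold). Lower in both were Icam1, Rnd1, Il15, Selp, Irf1 and Bcl3. Kdm5d was the 1 gene called in opposite directions, lower in AAV-XBP1S and higher in AAV-ATF6N. Both comparisons share the AAV-GFP libraries. Independent lists of the same lengths, with no controls in common, would share 0.0909 genes higher and 0.0329 lower. Across the 12876 genes with at least 10 counts in every library, which are not independent replicates, the fold changes correlated with r = 0.525, against 0.50 in 20 simulations of unchanged groups with shared controls. It was 0.286 without AAV-XBP1S replicate 2 and 0.778 without AAV-GFP replicate 2, for which no simulations were run. Their covariance was 0.195 against a simulated 0.0903, a difference of 0.104. The simulations gave all groups the same dispersion per gene. The measured AAV-GFP replicates differed more (SD of the log2 difference 1.04) than those of AAV-XBP1S (0.717) and AAV-ATF6N (0.558). The simulated values can therefore lie too low, and the difference in covariance cannot be read as a shared response. With 2 AAV-GFP libraries the controls could not be split into pairs, so part of the overlap may come from the shared controls. The counts of 12 higher and 8 lower in both became 15 and 15 without AAV-GFP replicate 1, 136 and 49 without AAV-GFP replicate 2, 1 and 0 without AAV-XBP1S replicate 1 or replicate 2, and 3 and 0 without AAV-ATF6N replicate 1 or replicate 2.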

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

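The counts of called genes depended on the processing more than the direction of these genes did: no gene called as reported changed sign in any alternative. Those genes were picked by their effects in these same libraries, and some genes not called did change sign (below). Called genes higher and lower are given in the order AAV-XBP1S against AAV-GFP, AAV-ATF6N against AAV-GFP, and AAV-ATF6N against AAV-XBP1S, where the values as reported were 26 and 20, 51 and 24, and 25 and 8. Without a filter on low counts they were 137 and 96, 226 and 122, and 175 and 283. With DESeq2 they were 306 and 214, 353 and 240, and 321 and 518. With only the groups compared in the fit they were 8 and 5, 6 and 2, and 275 and 391. With the gene-length offset, chosen after seeing the data, they were 125 and 164, 132 and 92, and 257 and 349. Without both libraries with the most Rn45s, AAV-GFP replicate 1 and AAV-XBP1S replicate 1, also chosen after seeing the data, they were 2054 and 2502, 2147 and 1906, and 2883 and 1972. Leaving out each library in turn gave 1 to 163 higher and 1 to 79 lower, 4 to 1515 and 0 to 1537, and 1 to 278 and 0 to 411. Where a group is left with 1 library, that library is assumed to vary like the other groups. Between AAV-ATF6N and AAV-XBP1S, where 25 higher and 8 lower were reported, lower genes outnumbered higher ones without a filter, with DESeq2, with only the groups compared, with the offset, with the replicate block and without either AAV-GFP library, so the balance of that comparison is not a stable result. DESeq2 size factors, the stricter filter and robust spread kept every count of called genes within 1.5 times of the value reported. Of the 46, 75 and 33 called genes, 46, 72 and 33 were still called with the gene-length offset, 40, 63 and 28 with robust spread, and 13, 8 and 33 with only the groups compared. AAV-GFP enters the direct comparison only through the shared spread and the normalization. Its 33 calls became 666 with only the groups compared. The AAV-GFP replicates differed most, with a chi-square per gene of 749 against 282 in AAV-XBP1S and 11.8 in AAV-ATF6N. The number of direct calls thus depends on including the AAV-GFP libraries. The cause of the other moves was not tested.

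The replicate number as a block gave 92 and 73, 163 and 74, and 145 and 211 calls. The same-numbered libraries' deviations correlated at 0.379 for AAV-GFP with AAV-XBP1S, -0.0402 for AAV-GFP with AAV-ATF6N and -0.0480 for AAV-XBP1S with AAV-ATF6N. Replicates 1 of AAV-GFP and AAV-XBP1S, the libraries with the most Rn45s, thus deviated alike, for a reason that was not tested. The labels do not say what the numbers mark and AAV-ATF6N showed no such link, so the numbers were not taken to pair the libraries. With the block, 43 genes were higher and 21 lower in both comparisons against AAV-GFP, and the atrial markers were called higher in AAV-XBP1S than in AAV-GFP (median 0.65, camera adjusted p = 0.0424), the 1 list call that the block changed. Atf6 passed in AAV-ATF6N against AAV-GFP with the block (1.51, edgeR adjusted p = 0.0203).

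Genes higher and lower in both comparisons, 12 and 8 as reported, were 69 and 33 without a filter, 118 and 53 with DESeq2, 3 and 2 with only the groups compared, 40 and 29 with the gene-length offset, 945 and 951 without both libraries with the most Rn45s, and 1 to 136 and 0 to 49 with single libraries left out. The correlation of fold changes, 0.525, ran from 0.286 without AAV-XBP1S replicate 2 to 0.778 without AAV-GFP replicate 2. Of the 19, 18 and 18 lists called, 0, 0 and 0 were called with an estimated correlation, whose smallest adjusted p were 0.0698, 0.0529 and 0.0982. Leaving out single libraries gave 12 to 19, 14 to 18 and 13 to 19 called lists, and fry 16, 13 and 16. These totals include lists newly called there, so they are not counts of the reported calls that held. Fry for a change in either direction, which asks another question, called 23, 19 and 22.

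Some log2 fold changes changed sign, and the cause was not tested. The genes below had not passed the test as reported, and where single libraries are left out the range over the 6 is given. In AAV-XBP1S against AAV-GFP, Hspa5 ran from -0.17 to 0.11 (above 0 without AAV-GFP replicate 2 or AAV-XBP1S replicate 1). Sec61b ran from -0.47 to 0.68 (above 0 without AAV-GFP replicate 1 or AAV-XBP1S replicate 2) and was 0.038 with the replicate block, 0.37 with the offset and 0.41 without both libraries with the most Rn45s. Atf4 ran from -0.53 to 0.27 (above 0 without the same libraries as Sec61b) and was 0.043 without both. Myh6 ran from -0.27 to 0.65 (below 0 without AAV-GFP replicate 1 or AAV-XBP1S replicate 2). Myh7 ran from -0.36 to 0.31 (above 0 without AAV-GFP replicate 1 or AAV-XBP1S replicate 1) and was 0.47 without both libraries with the most Rn45s. Atp2a2 ran from -1.05 to 0.050 (above 0 without AAV-GFP replicate 2). Ryr2 ran from -0.48 to 0.42 (above 0 without AAV-GFP replicate 1) and was 0.37 without both. Gfpt1 ran from -0.039 to 0.83 (below 0 without AAV-XBP1S replicate 2).

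In AAV-ATF6N against AAV-GFP, Atf4 ran from -0.46 to 0.36 (above 0 without AAV-GFP replicate 1) and was 0.14 with the offset and 0.36 without both. Atp2a2 ran from -0.083 to 0.99 (below 0 without AAV-GFP replicate 1) and was -0.083 without both. Ryr2 ran from -0.27 to 0.66 (below 0 without AAV-GFP replicate 2) and was -0.079 with the offset. In AAV-ATF6N against AAV-XBP1S, Edem1 ran from -0.15 to 0.42 (below 0 without AAV-XBP1S replicate 1) and was -0.058 with the offset and -0.10 without both. Atf4 ran from -0.12 to 0.27 (below 0 without AAV-XBP1S replicate 2). Gfpt1 ran from -0.084 to 0.79 (below 0 without AAV-XBP1S replicate 1) and was -0.039 without both. Of the lists, the proteasome, called lower in AAV-ATF6N than in AAV-GFP, had a median of 0.043 with the offset (camera adjusted p = 0.580). Oxidative phosphorylation, not called between AAV-ATF6N and AAV-XBP1S, was called higher by camera without AAV-XBP1S replicate 1 (median 0.15, adjusted p = 0.0355), with the offset (0.16, adjusted p = 0.000151) and without both (0.19, adjusted p = 4.64e-05), but lower without AAV-XBP1S replicate 2 (median -0.42, adjusted p = 0.0280).

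Depth was 67702482 to 112049342 counts per library, and a floor of 3 counts came to 0.0305 to 0.0459 CPM per library. Replicates differed by more than counting error, with a chi-square per gene of 749 in AAV-GFP, 282 in AAV-XBP1S and 11.8 in AAV-ATF6N. The log2 difference of replicate 1 from replicate 2 followed gene length, with Spearman correlations of -0.409 in AAV-GFP, -0.452 in AAV-XBP1S and 0.157 in AAV-ATF6N. Longer genes were thus relatively lower in replicate 1 of AAV-GFP and AAV-XBP1S. How far depth limits the calls was not tested.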

Other observations

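Of the tests weighed here, those chosen only after the result was seen were the endothelial markers and the ATF6N against XBP1S difference for the NF-kB targets, both tests of other cells and the test of gene length for the cell cycle genes, and the tests of carried-over reads and of a mixture for the Y-linked genes; the gene-length offset itself was also chosen after seeing the data. Bhlha15, singled out after its values were seen, encodes a transcription factor of secretory cells (mm10 chromosome 5, 144190286 to 144194441). It stood at 4.60 ± 0.199 CPM in AAV-XBP1S, 0.113 ± 0.0560 CPM in AAV-ATF6N and 0.0102 ± 0.0144 CPM in AAV-GFP. Its 803 counts in AAV-XBP1S against 2 in AAV-GFP gave a ratio of 389.6, with a counting interval of 108 to 3220. By edgeR it was higher in AAV-XBP1S than in AAV-GFP (adjusted p = 0.0153) and than in AAV-ATF6N (adjusted p = 0.0424). These calls were lost, with the same sign, without AAV-XBP1S replicate 1 (adjusted p = 0.246 and 0.382) or replicate 2 (0.240 and 0.328), and the second also without AAV-ATF6N replicate 1 (0.471) or replicate 2 (0.367), where a group is left with 1 library.

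NF-kB targets were lower in both treated groups, and 12 of them, among them Icam1, Selp, Irf1 and Il15, were noticed first (medians -2.91 and -2.18). A list of 27 tested targets not yet looked at was lower in both comparisons, with medians of -0.36 and -0.43 and a larger camera p of 0.00079 (0.0277 and 0.0327 with an estimated correlation). More endothelial cells in AAV-GFP are argued against for AAV-XBP1S by the endothelial median of 0.459, but stay open for AAV-ATF6N, where that median was -0.53, and the gene length trend is argued against by a larger median of -0.42 with a gene-length offset. A difference between the animals or handling of the shared controls and the treated libraries stays open. The first-noticed targets differed by a median of 0.18 between the treated groups. They were noticed as low in both groups, so that value cannot decide the question. The targets not yet looked at differed by a median of 0.077. A lower NF-kB response to both factors may be one reading, and a higher one in the 2 AAV-GFP libraries for another reason is as open.

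Cell cycle genes were higher in both treated groups, in cells sorted as cardiomyocytes; Top2a stood at 0.331 CPM in AAV-GFP, 6.54 in AAV-XBP1S and 6.73 in AAV-ATF6N, beside 98.3, 162 and 84.4 for the endothelial Pecam1. In AAV-ATF6N, more cells of every other type alike are argued against by the endothelial median of -0.53, but the fibroblast (0.39), extracellular matrix (0.64) and epicardial and Schwann cell (1.05) lists were called higher, the matrix at 0.30 and 0.96 without AAV-GFP replicate 1 and 2, while the fibroblast call was lost without either and its median was 0.15 without replicate 1. In AAV-XBP1S the same test first came out in favour of that explanation, with all 4 marker medians above 0 and the lowest at 0.41. A further bound was then added after that result was known. The cell cycle median exceeded the highest marker median by 1.02 (standard error 0.313). That standard error is the one of means over genes, not of the fit, and holds no spread between libraries. Since that bound was set after the first outcome, it argues only against such cells as the whole cause, and in both groups a change in the cell types that rose stays open. Low values in AAV-GFP replicate 1 are argued against by the smaller median of 1.5 without it, and the gene length trend by 1.47 with the offset. Both AAV-GFP libraries were low, with Top2a at 0.142 CPM in replicate 1 and 0.519 CPM in replicate 2. A difference between the animals or handling of these shared controls and the treated libraries was not tested and stays open. No biological explanation was tested.

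Y-linked transcripts and Xist differed between the groups. A different sex of the animals behind the AAV-XBP1S and AAV-ATF6N libraries predicts higher X-linked genes that escape inactivation in AAV-XBP1S, and their median difference was -0.42 (Kdm6a -0.49, Eif2s3x -0.35, Ddx3x -0.68, Kdm5c 0.11), although none passed by edgeR. Reads carried over from AAV-ATF6N into AAV-GFP are argued against by Derl3, which reached at most 0.323% of its AAV-ATF6N level in AAV-GFP, where Ddx3y reached 12.6% and 22.9%. A single mixture of male and female cells in each AAV-GFP library stays open: the shares of 4 Y-linked genes differed 1.86 times in replicate 2 and 11.7 times in replicate 1. AAV-XBP1S replicates 1 and 2 held 2 and 0 counts of Ddx3y and 4014 and 1650 of Xist, the pattern of female cells. AAV-ATF6N replicates 1 and 2 held 7626 and 5856 of Ddx3y and 16 and 6 of Xist, that of male cells. The direct comparison thus sets these patterns against each other. Sex may contribute to all comparisons, and the design holds no test that separates it from the vectors.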
